A study of Mus musculus with 2 samples.

How the data were processed

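Genomic DNA of E14 cells, an established mouse embryonic stem cell line, was profiled for 5-hydroxymethylcytosine (5hmC), an oxidised form of 5-methylcytosine made by the TET enzymes. Per the labels' protocols, 100 ng of DNA from cells at passage 12 was glucosylated, which turns 5hmC into its glucosylated form. The DNA was then cut with AbaSI, an endonuclease that recognises this modified base and cuts at a set distance from it. Per the labels' protocols, a biotinylated adapter was ligated to the cut ends, the DNA was sheared to about 300 bp and captured on streptavidin, and the library was amplified for 16 PCR cycles and sequenced on an Illumina HiSeq instrument. The 2 libraries were labelled as replicates 1 and 2 of 1 group. Nothing in the labels says whether they came from separate cultures.

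Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie were used and the genome build was mm9. The version of the aligner, any filter on reads, the treatment of PCR copies and the rule that turned cut positions into cytosines are not given in the sources used here. The values used here are whole-number read counts, 1 per listed cytosine, as deposited by the authors without scaling. Each deposited line gives a chromosome, a position, the dinucleotide that begins with the cytosine (CG, CA, CC or CT), the read count, the strand and a class code. The codes are 1CG, 2CG, CGCH, 1CH and 2CH. Their meaning is not given in the sources used here. For 2CG and 2CH it was read from the distances between sites and their equal counts (see the report), and for the other codes it stays unknown. The table has 1 count column for the whole series and does not keep the 2 libraries apart. How the libraries were joined is not given in the sources used here. No replicate error could therefore be computed, no fit leaving out a library was possible, and no test between samples was made. The lowest listed count was 2. A cytosine without a line is not a measured 0, since the authors' minimum for listing and their rule for assigning reads to cytosines are not stated. The build was checked on the positions. The last listed cytosine of chromosome 1 is at 197194906. The gene table at hand is of another assembly, and none of its coordinates were used.

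Positions were converted to 1-based coordinates. The table was read as deposited and all sites were kept in the main analysis. The depth is the total of 176006227 reads summed over 13025343 sites, with a median of 9 reads per site. For shares, exact Clopper-Pearson intervals at a level of 95% are given. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The spread along the genome is given as the SD or range over the 19 autosomes, or as a bootstrap over 5 Mb blocks of a chromosome with 1000 draws. Densities per megabase use the span from the first to the last listed site of a chromosome. Both strands of a CG were joined into a dyad when a plus-strand cytosine had a minus-strand cytosine 1 base to its right. Autosomal windows of 100 kb were counted from position 1, with windows without a site entered as 0. A site was said to have a close neighbour when another listed site lay within 100 bp, and the same share was computed for positions drawn uniformly over each chromosome's span. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

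The functions were tested on simulated sites. With 40.0% of simulated dyads listed on both strands, 40.1% were recovered. With partners planted 22 bp away for 30.0% of plus-strand sites, 30.0% were recovered. With reads scaled by 1.5, the mean excess of reads above 20 rose by a factor of 1.49, and with reads scaled by 0.5 the factor was 0.537. The simulated counts had a chosen distribution without PCR copies, so these factors need not hold for the listed counts.

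The comparisons, the alternatives and the rule for named regions were fixed before the data were examined. The rule named the 10 autosomal windows of 100 kb with the most reads and the 5 with the fewest, leaving out the first and last window of each chromosome, and the 5 sites with the most reads. The planned analyses of gene features, transcription start sites and gene lists were not run, because no annotation of mm9 was used here. For the same reason, regions are given by coordinates without gene names, no density per CG in the genome was computed, and CH sites were not split into CHG and CHH. The agreement of the replicates was not analysed, because the table pools them. Alternatives were minimum counts of 2, 5 and 10 reads, each site counted once, the top 0.1% of sites (those above 168 reads) left out, other window sizes and neighbours on 1 strand only. Alternatives chosen after seeing the data gave the 2CG and 2CH classes a weight of 0.5, or left out the chromosome 2 window with the most reads, mitochondrial DNA or the 2CG class. For the mean excess of reads on X, 2 windows were also left out in turn after the ratio over all windows had been seen.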

Results

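The series mapped 5-hydroxymethylcytosine at single cytosines in E14 mouse embryonic stem cells by AbaSI digestion and sequencing. It comprised 2 libraries of 1 group, and the deposited table held their reads as 1 count per cytosine. There was thus no contrast between conditions. The comparisons the data allow are between sequence contexts, strands, chromosomes and regions of the same genome. The table listed 13025343 cytosines with 176006227 reads in total. Counts ran from 2 to 426413 reads per site, with a median of 9 and quartiles of 6 and 16. The 1% of sites with the most reads held 9.74% of all reads, and 8.12% once the chromosome 2 window described below was left out. All values refer to the pooled table and have no replicate error.

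The first comparison was between cytosine contexts. CG cytosines made up 94.0% of the listed sites (95% interval 93.997 to 94.023) and 95.7% of the reads (95.743 to 95.749). These shares depend on how the authors assigned reads to cytosines, a rule not given in the sources used here. Over the 19 autosomes the CG share of sites ranged from 91.8% on chromosome 8 to 95.8% on chromosome 10, with an SD of 0.966 percentage points. The remaining 780199 sites were CA, CT or CC cytosines, together called CH. CA was the most frequent of these, with 407560 sites or 52.2% of the CH sites (52.1 to 52.3). CT followed with 266884 sites (34.2%) and CC with 105755 sites (13.6%). The frequencies of CA, CT and CC in the genome were not used here, so these shares are not rates per cytosine. CH sites carried fewer reads than CG sites, with a median of 5 against 10 reads and a mean of 9.60 against 13.8. The CG share of sites rose to 97.2% when at least 10 reads were required.

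The class codes divided the CG sites into 3 groups and the CH sites into 2. The class CGCH was the largest, with 6708033 sites or 51.5% of the total, a median of 10 reads and a mean of 13.3. Its code names both CG and CH, and all its sites were listed as CG, so the CG shares above rest on that assignment. The class 1CG held 4539597 sites (34.9%) with a median of 9 reads and a mean of 12.0. The class 2CG held 997514 sites (7.66%) but 14.3% of the reads, with a median of 16 and a mean of 25.2 reads per site. The CH classes 1CH and 2CH held 298710 and 481489 sites, each with a median of 5 reads.

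**Figure D1:**
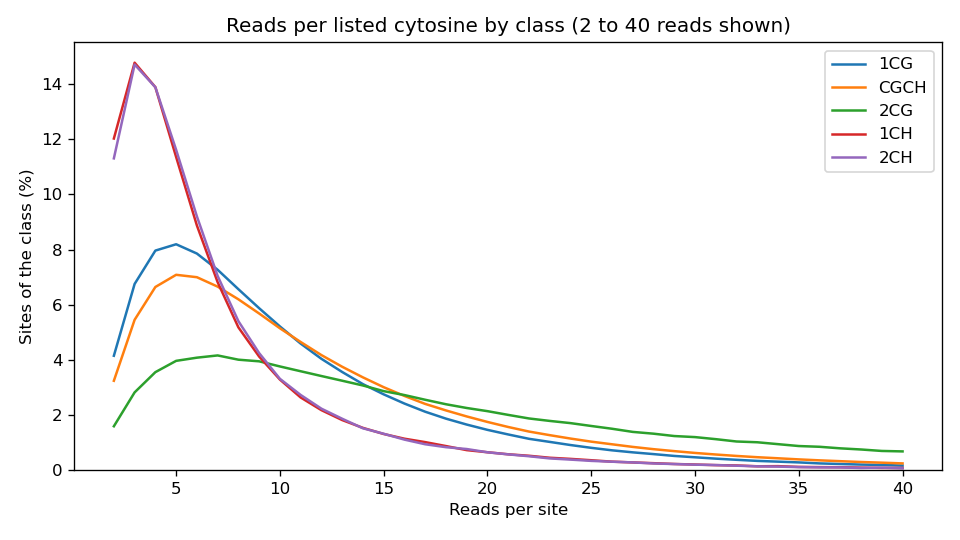
Distribution of reads per listed cytosine for each class code. The x axis gives reads per site from 2 to 40 and the y axis the percentage of the sites of that class. The lines of 1CH and 2CH peak at low counts (14.8% and 14.7% of their sites have 3 reads), while 2CG sites extend furthest to the right, with a median of 16 reads.

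The class codes differed in how sites were placed on opposite strands. In the class 2CG, 34.1% of plus-strand sites had a minus-strand site of the same class 22 bp to the right, and 32.6% had one at 23 bp. Of these pairs, 93.8% and 97.6% carried exactly equal read counts. In 2CH the corresponding shares were 27.6% and 31.2%, with equal counts in 88.3% and 93.1% of the pairs. Over offsets of 21 to 25 bp the shares summed to 87.8% in 2CG and 88.9% in 2CH. In 1CG, CGCH and 1CH they summed to 0.843%, 0.615% and 0.409%. Sites of the 2CG and 2CH classes were thus mostly listed as pairs of cytosines on opposite strands with equal counts. If each such pair stands for 1 set of reads, the totals count it at both cytosines. The total fell to 161389465 when these sites were given a weight of 0.5. In all CG classes together, 54.1% of plus-strand sites had a minus-strand site at an offset of 1 bp, the other strand of the same CG. Equal counts at that offset occurred in 4.43% of these pairs.

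**Figure D2:**
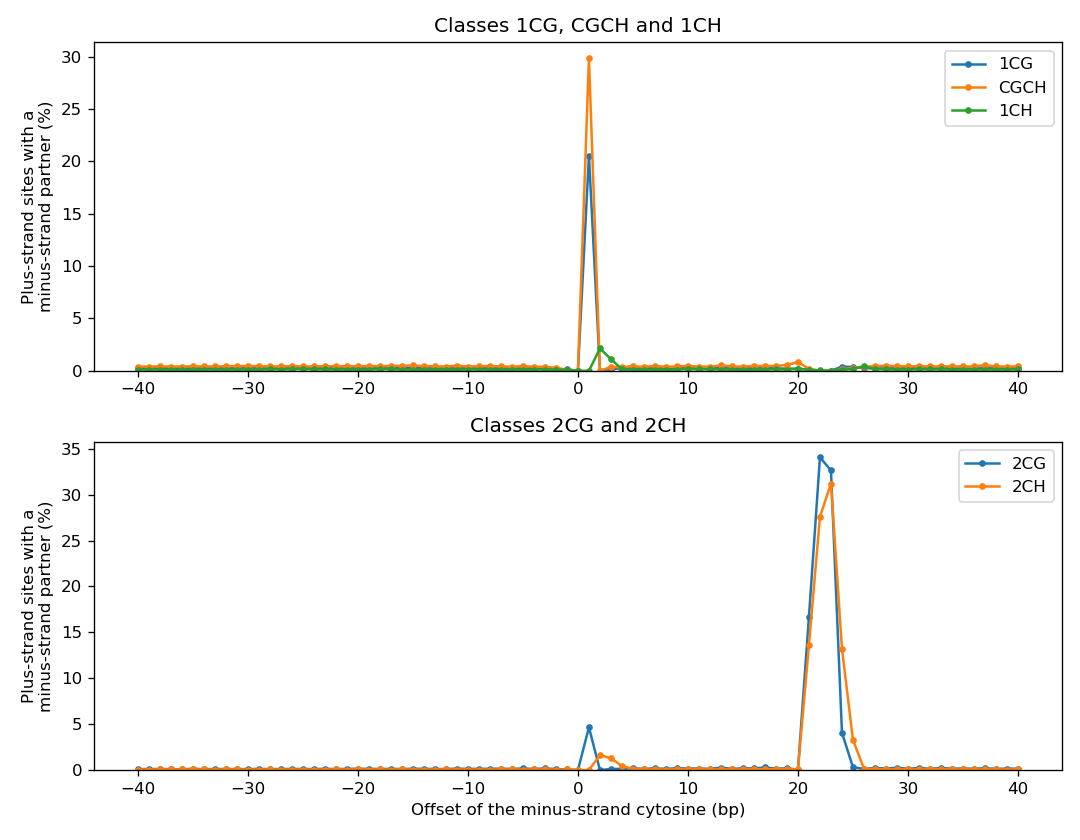
Share of plus-strand sites that have a minus-strand site of the same class at each offset. The x axis gives the offset of the minus-strand cytosine in bp, from 40 to the left to 40 to the right, and the y axis the percentage of plus-strand sites. CGCH and 1CG peak at 1 bp (29.9% and 20.5%), and 2CG and 2CH peak at 22 and 23 bp.

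Strand symmetry was compared within CG dyads. Plus and minus strands were listed about equally, with 50.02% of sites (49.988 to 50.042) and 50.09% of reads (50.082 to 50.097) on the plus strand. Of 8928957 CG dyads with a listed site, 3316187 or 37.1% (37.108 to 37.171) were listed on both strands. The mean over the 19 autosomes was 37.0% ± 3.61 (SD, n = 19 chromosomes). The highest shares were 48.1% on chromosome 11 and 44.4% on chromosome 8, and the other 17 autosomes lay between 33.7% and 38.3%. The X chromosome had 17.9%. Across dyads listed on both strands, the read counts of the strands had a Spearman correlation of 0.24, against 0.00 ± 0.00267 (SD over 19 autosomes) after partners were shuffled within chromosomes. Dyads are not independent replicates and no p-value is given. Counts differed by more than 3-fold between the strands in 22.2% of these dyads (22.182 to 22.271). Splitting the reads of each dyad at random between its strands gave 2.59%, a value that covers counting error only, since PCR copies of a molecule are not independent reads. A dyad listed on 1 strand is not shown to lack 5hmC on the other, because the minimum for listing is unknown. The share listed on both strands fell to 26.9% when at least 10 reads were required of each site.

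Listed sites lay close together. The median distance to the next site on the autosomes was 35 bp and the 90th percentile was 407 bp. Of all sites, 86.9% (86.866 to 86.903) had another within 100 bp, against 65.7% for positions drawn at random. With each CG dyad counted once, the share was 76.6% (76.605 to 76.658). Neighbours at 1 bp made up 25.7% of all distances, most of them the strand partners of the 3316187 dyads listed on both strands. A second maximum lay at 22 bp with 1.52%, compared with 0.479% at 30 bp. The random positions were not restricted to CG dyads, so the excess includes the clustering of CG itself. On a single strand, 67.1% of sites had a neighbour within 100 bp. The random share was drawn for as many positions as all sites. It is therefore no baseline for this value or for dyads counted once, which have fewer positions.

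The chromosomes differed in reads per megabase, and chromosomes 11 and 8 had the most among the autosomes. Chromosome 11 had 152310.5 reads per Mb and chromosome 8 had 111964.4, which is 2.16 and 1.59 times the median autosome. The other 17 autosomes ranged from 50043.1 on chromosome 3 to 86330.3 on chromosome 19. With the top 0.1% of sites left out, the bootstrap intervals over 5 Mb blocks were 115304.8 to 179360.2 for chromosome 11 and 83378.2 to 135095.9 for chromosome 8. The upper bounds of 7 of the other 17 autosomes reached the interval of chromosome 8, the highest being 110209.9 on chromosome 19, and 0 of the 17 reached that of chromosome 11. Chromosomes 11 and 8 also had the most sites per Mb (8961.9 and 7116.6), against 4097.2 to 6542.8 on the other 17. Reads per site separated them more clearly. With the top 0.1% of sites left out, CG sites of the class 2CG had a mean of 30.4 reads on chromosome 11 and 28.8 on chromosome 8. On the other 17 autosomes this mean was 22.7 ± 0.446 (SD, n = 17 chromosomes), with a highest value of 23.4 on chromosome 17. CH sites were more frequent on both as well, with 593.7 per Mb on chromosome 11 and 582.0 on chromosome 8, against 226.5 to 357.9 on the other 17. Without the top 0.1% of sites, mean reads per CH site were 7.63 on chromosome 11, within the 6.73 to 8.35 of the other 17, and 8.43 on chromosome 8, just above that range.

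**Figure D3:**
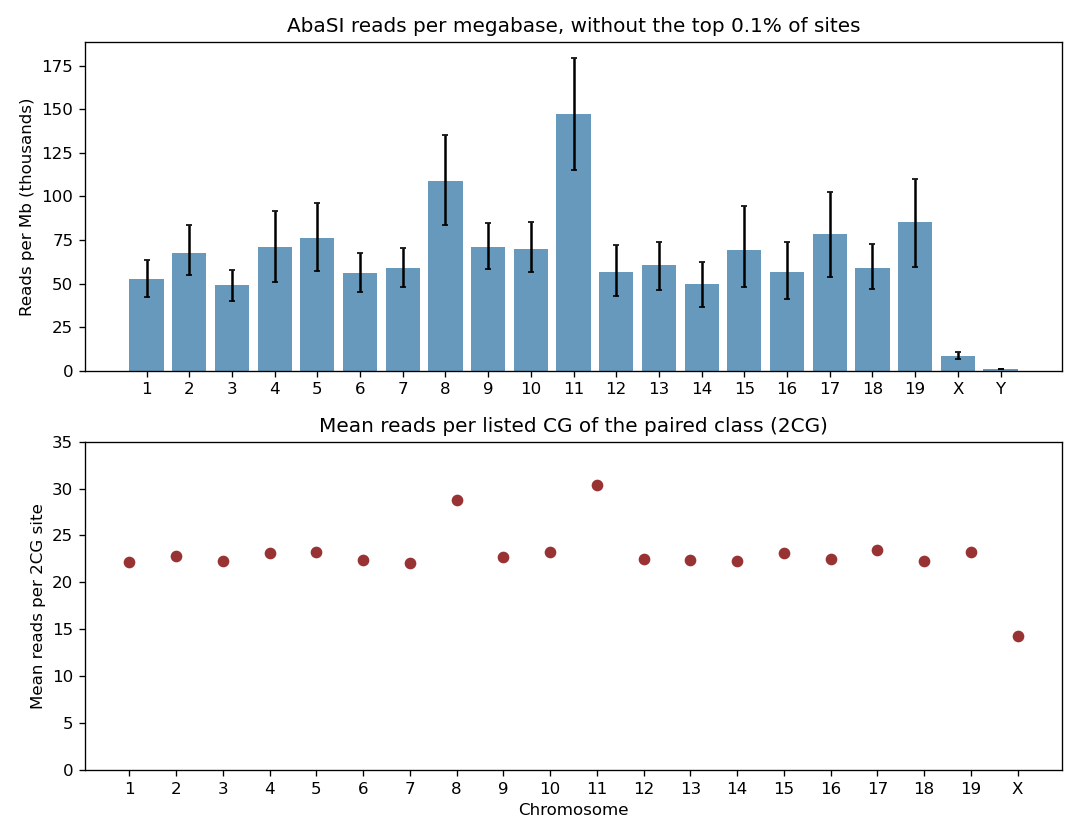
The upper plot gives reads per Mb, in units of 1000, for each chromosome without the top 0.1% of sites, with bars for the pooled value and error bars for the 95% bootstrap interval over 5 Mb blocks. The Y chromosome has 1 block and no interval. The lower plot gives the mean reads per site of the 2CG class on the autosomes and X, also without the top 0.1% of sites. Chromosomes 8 and 11 lie above the other autosomes at 28.8 and 30.4 reads, and X lies below at 14.3.

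The X chromosome lay below every autosome. It had 1016.5 sites and 9019.1 reads per Mb, which is 0.189 and 0.128 times the median autosome. With the top 0.1% of sites left out, its bootstrap interval of 829.1 to 1210.8 sites per Mb was far below that of chromosome 3, the autosome with the lowest upper bound, at 3445.5 to 4706.1. Sites of X also carried fewer reads, with a median of 7 per CG site against 9 to 12 on the autosomes. The window of X from 166400001 to 166500000, named after its values were seen, held 1184 sites and 40485 reads. The median X window with a site held 58 sites and 424 reads. Without that window X had 1009.3 sites per Mb. The Y chromosome had 322 listed sites with 2831 reads between positions 28369 and 2901752.

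**Figure D4:**
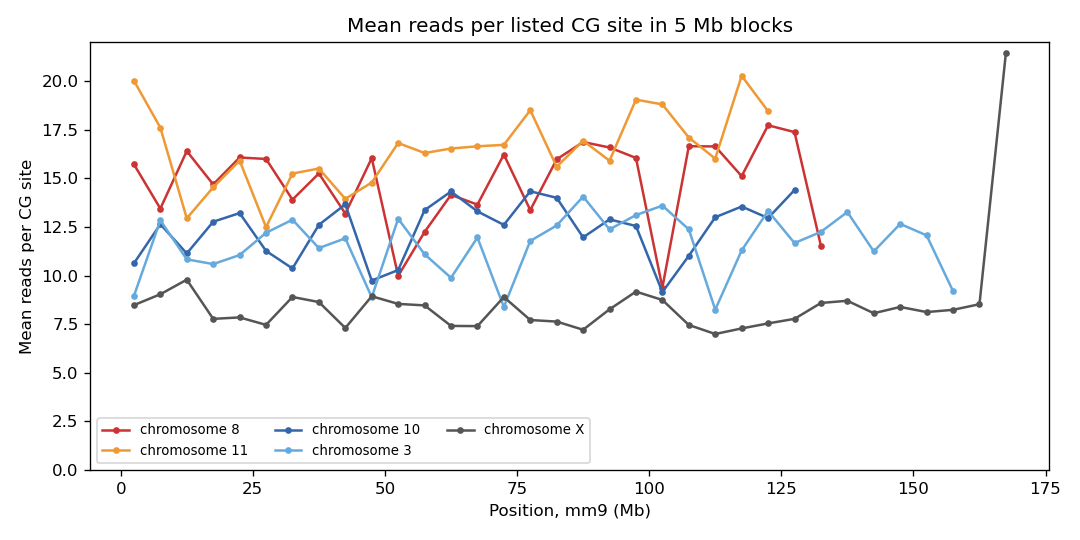
Mean reads per listed CG site in 5 Mb blocks along chromosomes 3, 8, 10, 11 and X, without sites above 168 reads. The x axis gives the mm9 position in Mb and the y axis mean reads per CG site. Chromosome X stays below 10 reads except in its last block, which has a mean of 21.5 over 1984 CG sites.

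Reads were spread unevenly along the autosomes. The 24161 windows of 100 kb had a median of 4116 reads, with 5% of windows below 368 and 5% above 22336, and 263 windows had no listed site. The coefficient of variation was 3.02, but a single window of chromosome 2 set this value. Without that window it was 1.17, and without the top 0.1% of sites 1.07. With the top 0.1% left out, the value was 1.27 in windows of 10 kb and 0.907 in windows of 1 Mb.

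The window with the most reads was chromosome 2 from 98500001 to 98600000, with 3145112 reads on 721 sites. CH cytosines made up 79.8% of its sites and 34.8% of its reads. The 5 sites with the most reads all lay there and were all CG. The highest was the plus-strand cytosine at position 98507264 with 426413 reads, or 0.242% of all reads. Its minus-strand partner at 98507265 had 244544 reads. The others were at 98507324 with 188753 reads, at 98507307 with 169463 and at 98502452 with 121463. The first windows of chromosomes 9 and 11, left out as chromosome ends, held 454999 and 259466 reads between positions 3000001 and 3100000. Among the windows kept, the second was chromosome 9 from 35100001 to 35200000, with 132895 reads on 677 sites. CH cytosines made up 19.9% of its sites and 51.3% of its reads. The third was chromosome 6 from 103500001 to 103600000, with 74785 reads on 167 sites, and a single site held 43.8% of its reads. Whether reads of repeated sequence or PCR copies gathered at these sites and windows was not analysed here. Their counts therefore do not measure the level of 5hmC at single cytosines.

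The next 7 windows were of another kind, with 2212 to 2833 sites each and a CH share of sites between 2.44% and 5.48%. All 7 lay on chromosomes 8 and 11. They were chromosome 11 from 117900001 to 118000000 with 69275 reads, and chromosome 8 from 123000001 to 123100000 with 60396 and from 122900001 to 123000000 with 56766. Then came chromosome 8 from 119800001 to 119900000 with 53627 reads, chromosome 11 from 119000001 to 119100000 with 53433, chromosome 8 from 125000001 to 125100000 with 52322 and chromosome 11 from 117100001 to 117200000 with 50778. In these windows the mean was 21.1 to 24.5 reads per site. Of the 100 interior autosomal windows with the most reads, 91 were on chromosomes 8 and 11, which hold 10.2% of such windows.

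At the other end, the 5 windows with the fewest reads had 1 site each. They were chromosome 5 from 94200001 to 94300000 and from 95000001 to 95100000 with 2 reads each, chromosome 4 from 111900001 to 112000000, and chromosome 7 from 10000001 to 10100000 and from 22100001 to 22200000 with 3 reads each. 3 windows in all had 3 reads. How much of each window reads can be mapped to was not analysed here, so these counts do not measure absence of 5hmC.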

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

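The tests in this part were chosen after the values they use were seen. Mitochondrial DNA, counted in the totals above but not compared on its own, held 59190 reads on 3297 listed cytosines. Of these, 2913 were CH and 384 CG, a CH share of 88.4% against 4.21% to 8.18% on the autosomes. CG sites had a mean of 21.5 reads and CH sites 17.5. Of the 205 CG dyads with a listed site, 179 were listed on both strands. CH sites numbered 1953 on the plus strand and 960 on the minus strand. CA, CT and CC made up 39.1%, 40.7% and 20.2% of the CH sites.

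A candidate explanation is cutting at a low rate that does not distinguish CG from other cytosines and is seen because mitochondrial DNA has many copies per cell. Without sites above 168 reads, the ratio of mean reads at CG to mean reads at CH sites was 1.24 there and between 1.53 and 2.24 on the autosomes. A ratio below every autosome was the result set for that explanation, but cutting wholly alike would give equal means. The ratio covers listed sites only and is not a rate of cutting. With all sites kept it was 1.23 there and 0.533 to 2.22 on the autosomes, 2 of which (chromosomes 2 and 9) lay below it. The range on the autosomes was 1.58 to 2.30 without the 5 autosomal windows with the most reads. In 5 of these 5 windows, chromosome ends included, CH sites made up more than 3 times the autosomal share of 5.99%. With all sites kept, the ratio of reads was 7.39, 2.87 and 11.7 in 3 of them, above the highest autosome, and 0.939 and 0.236 in the others. Reads were thus not alike at CG and CH in the 5 as a set. The ratio cannot separate cutting at all cytosines from 5hmC at CG in the same window, so it does not decide whether such cutting gave the CH sites. A low level of 5hmC at all mitochondrial cytosines would give the same values and stays open. The design has no sample without glucosylation or without 5hmC, and no biological explanation was tested.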

How the results depend on the processing

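Across 14 results and 82 alternatives, 44 values stayed within the spread used for comparison and 38 moved. That spread was the counting interval for shares, 1.5 times for the number of sites, the SD over autosomes for the other values, and any difference at all for the median per window. Because the counting intervals are narrow, most moves are small. A minimum of 2 reads changed nothing, since every listed site has at least 2. With each site counted once, chromosome 11 had 1.67 times the median autosome in place of 2.16, and the chromosome 8 ratio ranged from 1.32 to 1.71 over its alternatives. For X the SD over autosomes exceeded the ratio itself, so it could not register a fall: the ratio of sites went from 0.189 to 0.112 at a minimum of 10 reads, and the ratio of reads from 0.128 to 0.0956 there and to 0.189 with each site counted once. With minimums of 5 and 10 reads, the median per site was 11 and 16 reads, the top 1% held 9.27% and 8.93% of reads, CG made up 95.7% and 97.2% of sites and 96.1% and 96.7% of reads, dyads on both strands 34.4% and 26.9%, the correlation of strands 0.21 and 0.17, close neighbours 85.6% and 81.3%, and median reads per window 3837 and 2818. With 10 reads, 6448527 sites remained. A higher minimum removes the sites with few reads, so these values describe other sets of sites, and what caused each change was not tested. Counting each site once gave a CG share of 94.0%, a coefficient of variation of 0.863 and a median of 389 sites per window. Leaving out the top 0.1% of sites gave a CG share of reads of 96.5%, a coefficient of 1.07 and a median of 4055. Windows of 10 kb and 1 Mb gave coefficients of 8.99 and 1.25, and neighbours on the same strand 67.1%. The following were chosen after seeing the data. A weight of 0.5 for 2CG and 2CH sites gave 8.62% in the top 1%, 96.6% of reads at CG and a median of 3734 per window. Without the chromosome 2 window these were 8.12%, 96.3% and 4115, and the coefficient was 1.17. Without mitochondrial DNA, CG made up 94.0% of sites (94.031) and 95.8% of reads. Without the 2CG class, 34.4% of dyads were on both strands with a correlation of 0.27. No alternative restricted to unmasked sequence, to base pairs or to gene models was run, since no mm9 sequence or annotation was used here. The pooled table allowed no fit without a replicate. Depth limits mainly sites near the unstated minimum, and the 5th percentile of reads per site was 3.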

Other observations

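All tests of this part were chosen after their values were seen, except the matched windows, the mean excess of reads above 20 and the thinned autosomes. Reads at neighbouring CG cytosines were weakly similar, and the similarity faded slowly with distance. Over the 19 autosomes, with 2CG sites left out, log2 reads at CG sites 1 bp apart (both strands of a dyad) had a Pearson correlation of 0.26 ± 0.0148 (SD, n = 19 chromosomes). It was 0.16 ± 0.0106 at 2 to 10 bp, 0.14 ± 0.00976 at 26 to 50 bp, 0.10 ± 0.00881 at more than 200 and up to 500 bp and 0.07 ± 0.00744 at more than 5000 and up to 10000 bp. At 21 to 25 bp it rose to 0.23 ± 0.0119, and to 0.48 ± 0.0190 with 2CG sites included. Listed 2CG pairs mostly carry equal counts at this distance. In 1CG and CGCH, pairs at 21 to 25 bp had equal counts in only 6.58% and 6.66% of cases. What raised the correlation without 2CG sites was not tested.

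Over 23860 windows of 100 kb with a site, CG and CH reads had a Spearman correlation of 0.67, and 0.55 to 0.73 within single autosomes. A rank correlation does not show that CH rose in proportion to CG, and windows are not independent replicates.

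Chromosomes 8 and 11 had more sites and more reads per site than the other autosomes. A few very high sites are argued against, since without the top 0.1% of sites reads per Mb were still 1.798 and 2.44 times the median of the other 17, whose highest was 1.41. Local stretches are argued against for both jointly, with 94.2% of 52 blocks of 5 Mb above the median block of the other autosomes, and for chromosome 11 alone at 100%, while chromosome 8 alone, at 88.9%, fell short of the 90% set for this. A denser set of listed sites is argued against as the whole cause by windows matched on CG sites per Mb, at 1.16 and 1.18 times the other autosomes (whose own ratios were 0.987 to 1.02), and a rise of sites at CG alone by CH sites per Mb at 2.02 and 2.06 times. A rise of reads per site at CG alone stays open. Without the top 0.1% of sites, reads per CH site were 1.04 times the median of the other 17 on chromosome 11, within their range of 0.914 to 1.13, and 1.145 times on chromosome 8, just above it. An extra copy of each chromosome also stays open as a hypothesis. The mean excess of reads above 20 was 1.28 times on chromosome 8, between the bounds set in advance, and 1.35 times on chromosome 11, within the range set for 3 copies against 2. That range was set for both chromosomes jointly, so it was not met. Simulated reads at 3 copies against 2 gave 1.49, above both values. The simulation drew counts from a chosen distribution without PCR copies, not from the listed counts. What 3 copies against 2 would give in these data is unknown, so neither 1.49 nor the range set in advance decides the question. No karyotype or input library was analysed here.

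The X chromosome had fewer sites per Mb than any autosome, and a fall at CG alone is argued against, since CH sites per Mb were 0.133 times the median autosome and CG sites 0.193 times. A single copy as the whole cause is argued against only if 2 reads were enough for listing and each read stood for its own molecule. The sources used here do not state the floor, and PCR reads without molecular identifiers are not independent molecules. Under these conditions, autosomes thinned to a share of 0.5 of their reads kept at least 3590.0 sites per Mb, and X had 0.283 times that. A single copy as the cause of the lower reads per site stays open. Without sites above 168 reads, mean reads per site were 0.675 times the median autosome at CG and 0.629 times in the 2CG class. The mean excess of reads above 20 was 0.934 times the autosomes, past the bound of 0.8 set against a single copy in advance. Its bootstrap interval over 5 Mb blocks, computed afterwards, was 0.728 to 1.29. That interval includes the bound of 0.8 but lies wholly above the 0.35 to 0.65 set in advance for a single copy. Neither the range nor the bound was calibrated on the listed counts, so they do not decide on a single copy. After the ratio of 0.934 was seen, the X window with the most reads was left out, which left the ratio at 0.934. The unchanged value gives no sign that this window entered the ratio, so leaving it out was no check of the ratio. The window with the most sites, from 166400001 to 166500000, was then left out, which gave 0.759, also above the range for a single copy and below 0.8. The ratio thus depended on this window, which held 0.712% of the X sites. In it 65.2% of CG dyads were listed on both strands, against 17.9% on X, with a mean of 34.2 reads per site. Whether it has the same number of copies as the rest of X was not analysed here. The ratio of 0.934 and its interval include this window, so they may not describe the rest of X. A stricter listing rule, fewer CG or fewer mappable positions on X and less 5hmC there remain untested.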
